A study of Mus musculus with 2 samples.

How the data were processed

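Gene expression was measured on 2 two-colour Agilent whole mouse genome arrays that compared the same 2 RNA pools with the dyes swapped. Per the labels, aortas of 6 C57Bl/6 mice were perfused with a detergent to remove the endothelium and divided into the arch (root, arch and the first 2 mm of the thoracic aorta) and the central thoracic aorta (the next 6 mm). RNA of each region, with integrity numbers from 7.5 to 7.7, was pooled across the mice and 1 µg was amplified and labelled per dye. The arrays were read out with Agilent Feature Extraction 9.1.1.1, per the submitters' processing notes. The deposited scanner files give, per the file headers, the mean signal and the local background of each spot as an intensity in each dye. They also hold a log10 ratio of the processed Cy5 and Cy3 signals, as deposited by the authors. The series' value table was set against these ratios: it equalled the log10 ratio, turned to arch over thoracic aorta, in 99.9% of features on each array (tolerance 1e-06), and both of its medians are 0. Its scale and direction are not stated there and were found from this match. The direction follows the dyes in the labels. No genome build is named in the array files, so no coordinates are given.

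From the intensities, background was corrected by the normexp method (offset 50) and the ratios were normalised within each array by loess, with limma 3.58.1 in R 4.3.3 and with control spots at weight 0. Each array held 43790 spots, of which 41534 were gene spots. Control spots and spots flagged as outliers (20 and 4) were then left out, saturated spots were kept, the sign of array 2 was turned, and spots of a probe were averaged. A probe was kept if it was well above background on both arrays in at least 1 region, which kept 30521 of 41150 probes, and a gene took the value of its brightest kept probe. This left 21367 genes or transcripts, 20168 of them well above background in both regions on both arrays. Current symbols came from a RefSeq gene table (assembly GRCm38.p6), used for names only: 23134 spots were matched by accession, 10302 by name or synonym, and 8098 kept the name in the file. The gene reported as Cytl1 carries an older name in the files and was matched through a synonym. A gene for which every kept probe was well above background in 1 region only has only a bound, the brighter region's mean against the higher of its own level and the lowest signal well above background in the dimmer region, per channel after loess and Aquantile normalisation.

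The 2 arrays are a technical dye swap and count as 1 replicate, so no test, standard error or p-value is given. A gene was called higher or lower if its ratio was at least 1.5-fold in the same direction on each array. The arrays' ratios correlated across genes with r = 0.581 (Spearman 0.248; genes are not independent replicates), and half-differences had an SD of 0.07 on the log2 scale. Negative control spots kept 10.3 units above the local background in Cy5 and 27.1 in Cy3 on array 1, and 9.90 and 25.8 on array 2, while the median gene spot kept 39.2, 55.9, 43.4 and 54.4. Of the negative controls, 0% and 6.69% were well above background on array 1 and 1.91% and 10.8% on array 2, in Cy5 and Cy3. Gene spots near that level are therefore imprecise, and 17 of the measured genes were saturated on an array, none of them called.

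Before the data were examined, 29 gene lists (14 of pathways or gene families and 15 of cell types and controls) and the rule for named genes were fixed. A list was described by the median ratio of its measured members and its percentile among 10000 random lists of the same size matched on mean intensity in 20 bins, which describes these pools and is no test. The named genes are the 12 highest and the 12 lowest of the called genes with a symbol that were well above background in both regions on both arrays, up to 6 per direction with a bound, up to 4 members per list with the largest ratios, every measured Hox gene and the sex-linked controls. Acta2, Tagln, Ren2 and the members of later lists were named after their values were seen. A few genes that the rule picks are not reported here. Members not well above background in either region, such as Myh6 and Hoxd9, and 5 listed genes that were not found on the array by symbol (Bglap1, C4, Hspa1b, Hbb-b1 and Gapdh) were left out of their lists. Another 7 lists were chosen after seeing the data and are used only in the closing observations.

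The rules were tested on simulated data, dye-swap arrays made from the real signals with 200 genes changed among 21167 unchanged ones. For the simulated comparison of arch and thoracic aorta, the 1.5-fold rule recovered 59 of 66 genes changed 4-fold, 32 of 67 changed 2-fold and 4 of 67 changed 1.5-fold, with a median measured ratio of 1.26 for a true 2.00 at 4-fold. It called 0 of the unchanged genes. With an offset of 0 it recovered 66 of 66, 62 of 67 and 7 of 67, with a median of 1.90 for the true 2.00, and called 7 of the unchanged genes. Of 200 simulated unchanged lists 4% stood outside the central 95%, and 100% of 50 lists with raised members did. Most members of those raised lists were raised by 1.5-fold to 4-fold, and noise was independent between genes. These shares may therefore not carry over to the real lists. The alternatives tried were an offset of 0, no background subtraction, the scanner software's ratios, median centring, the series' value table, no filter on dim probes, a filter on both regions, the mean over probes, outlier spots kept, each array alone, folds of 2 and 1.3, the mean of the arrays, and lists without genes measured in 1 region only.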

Results

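RNA from the wall of the mouse aorta was compared between an atherosclerosis-prone region, the aortic arch, and an atherosclerosis-resistant region, the central thoracic aorta. The animals were C57Bl/6 mice, a common inbred strain, aged 16 weeks. Each region was represented by 1 pool of RNA from 6 mice (3 males and 3 females), and the same 2 pools were hybridised to 2 two-colour Agilent whole mouse genome arrays with the dyes swapped. The arch was in Cy5 on array 1 and in Cy3 on array 2. Median spot signals were 87.1 (Cy5) and 97.1 (Cy3) intensity units on array 1 and 91.1 and 94.9 on array 2, over local backgrounds of 48 and 41 on array 1 and 48 and 40 on array 2. Between 71.3% and 81.5% of gene spots per channel were well above background. Values are log2 ratios of arch over thoracic aorta averaged over the arrays, and the figure after ± is the distance of either array from that mean. That error is technical only: with 1 pool per region the difference between the regions has no biological replicate check, and the number of arrays limits the precision.

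The question of the comparison, from the labels, was which transcripts differ between the vessel walls of the prone and the resistant region in young wild-type mice. The thoracic pool held far more of the homeobox transcripts Hoxa7 and Hoxb7, transcription factors that mark position along the body axis, at 7.43-fold and 6.10-fold the arch level. Sfrp4, a secreted antagonist of Wnt signalling, was 5.23-fold higher in the thoracic pool. The arch pool held more Myl7, the atrial myosin light chain (5.04-fold), Cytl1, a small secreted protein of cartilage (3.87-fold), and Tnnt2, cardiac troponin T (3.02-fold). Transcripts typical of brown and white fat were also higher in the arch, with Cox7a1 at 1.85-fold and Adipoq at 1.58-fold.

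Of 21367 genes or transcripts measured, 55 were at least 1.5-fold higher in the arch on each array and 49 at least 1.5-fold lower, and 93.1% had a mean ratio within 0.2 of 0 on the log2 scale. The same rule applied to the dye instead of the region picked 0 genes. The genes highest in the arch included Myl7 (2.33 ± 0.01), Cytl1 (1.95 ± 0.00), Ren1, encoding renin (1.68 ± 0.04), Tnnt2 (1.59 ± 0.03) and Epyc, a small leucine-rich proteoglycan (1.42 ± 0.12). Others were the secreted glycoprotein Stc2 (1.26 ± 0.10), the glutathione S-transferase Gsta3 (1.12 ± 0.06) and the ubiquitin ligase Lnx1 (2.14-fold, ± 0.15 on the log2 scale). Igfbp2, which binds insulin-like growth factors, measured 1.07 ± 0.18, the membrane protein Flrt3 1.05 ± 0.08, the anticoagulant receptor Thbd 1.04 ± 0.01 and the kinesin Kif1a 1.00 ± 0.02. Other probes gave smaller values, down to 0.15 for Ren1, 0.19 for Flrt3, 0.11 for Kif1a, 0.48 for Lnx1 and 0.87 for Gsta3, and Flrt3 and Kif1a were not called as the mean of their probes. A probe named for the near-identical Ren2 gave 0.85 ± 0.05. The probes may not tell these sequences apart, so this value does not show that Ren2 itself was present.

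The genes lowest in the arch were Hoxa7 (−2.89 ± 0.21), Hoxb7 (−2.61 ± 0.25) and Sfrp4 (−2.39 ± 0.04). Mup1 (−1.83 ± 0.09) and Mup4 (−1.40 ± 0.08) are members of the large family of major urinary proteins, whose transcripts the probes may not tell apart. The fibulin Fbln7 measured −1.49 ± 0.08, the paired-box transcription factor Pax1 −1.43 ± 0.18 and Gpsm2, a modulator of G protein signalling, −1.30 ± 0.03. Shisa3 measured −1.15 ± 0.08 and Lgi2 −1.10 ± 0.03. Other probes were nearer to 0 for Mup1 (−0.64), Gpsm2 (−0.82) and Lgi2 (−0.59). Fhl2, a LIM-domain protein, measured −1.32 ± 0.11 at its brightest probe and 0.00 at another, so its probes disagree.

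**Figure D1:**
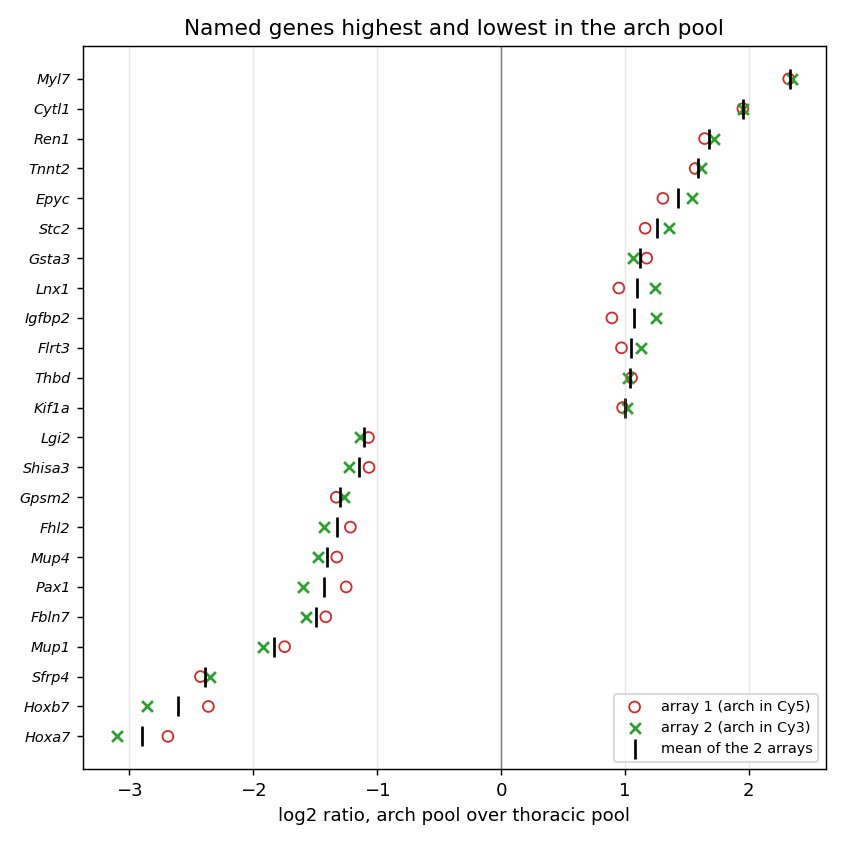
Log2 ratio of arch over thoracic pool (x axis) for the named genes highest and lowest in the arch (y axis), with array 1 as open circles, array 2 as crosses and their mean as a bar. The arrays lie close together beside the size of the ratios, from 2.33 for Myl7 to −2.89 for Hoxa7.

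Hox genes, which are ordered along the chromosome as they are used along the body axis, differed between the regions by member. In paralog groups 4 to 10, 5 of 18 measured genes were lower in the arch by the 1.5-fold rule and 0 were higher. Besides Hoxa7 and Hoxb7 these were Hoxc6 (−0.93 ± 0.10), Hoxb5 (−0.89 ± 0.00) and Hoxa5 (−0.70 ± 0.03). The other members lay from −0.22 (Hoxc9) to 0.22 (Hoxc5), apart from Hoxb8 and from Hoxd4 and Hoxd8, which were well above background in the arch pool only. With the scanner software's ratios Hoxc9 was −0.94 ± 0.26, Hoxa9 −0.66 ± 0.36 and Hoxc5 0.27 ± 0.15. The same ratios gave −3.49 for Hoxa7 and −3.28 for Hoxb7. They gave −1.79 for Hoxb5, −1.63 for Hoxc6 and −1.21 for Hoxa5. Hoxb8 measured −0.57 ± 0.08 at its brightest probe, which was not well above background in the arch, and −0.05 at another probe, which was so in both regions. The scanner software's ratio at the first of these Hoxb8 probes was −2.81 ± 0.28. Probes disagreed in sign for Hoxb6 (0.10 and −0.97) and Hoxb9 (0.11 and −0.08). In paralog groups 1 to 3, Hoxb3 was lower in the arch (−0.99 ± 0.06), Hoxb2 measured −0.37 ± 0.04 and Hoxa2 0.33 ± 0.02. The scanner software's ratios gave −2.43 ± 0.02 for Hoxb3, −0.43 ± 0.05 for Hoxb2 and 0.72 ± 0.04 for Hoxa2. Hoxa3 measured −0.01 and Hoxd3 0.07. The median of groups 4 to 10 was −0.07, at percentile 0.01 of matched random lists, with a mean of −0.46 and 9 of 18 members above 0. It was −0.15 without Hoxd4 and Hoxd8, and within the central 95% of random lists with an offset of 0 (percentile 3.82), the scanner software's ratios (5.56) or no filter on dim probes (−0.0060, percentile 27.3). The series' value table, which holds nearly the same ratios as the scanner files, gave −0.17 at percentile 0, with Hoxb8 read from the probe at −0.57 in place of the other. The median of groups 1 to 3 was 0.03, at percentile 84.6, while their mean was −0.15, so that median and mean differ in sign.

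**Figure D2:**
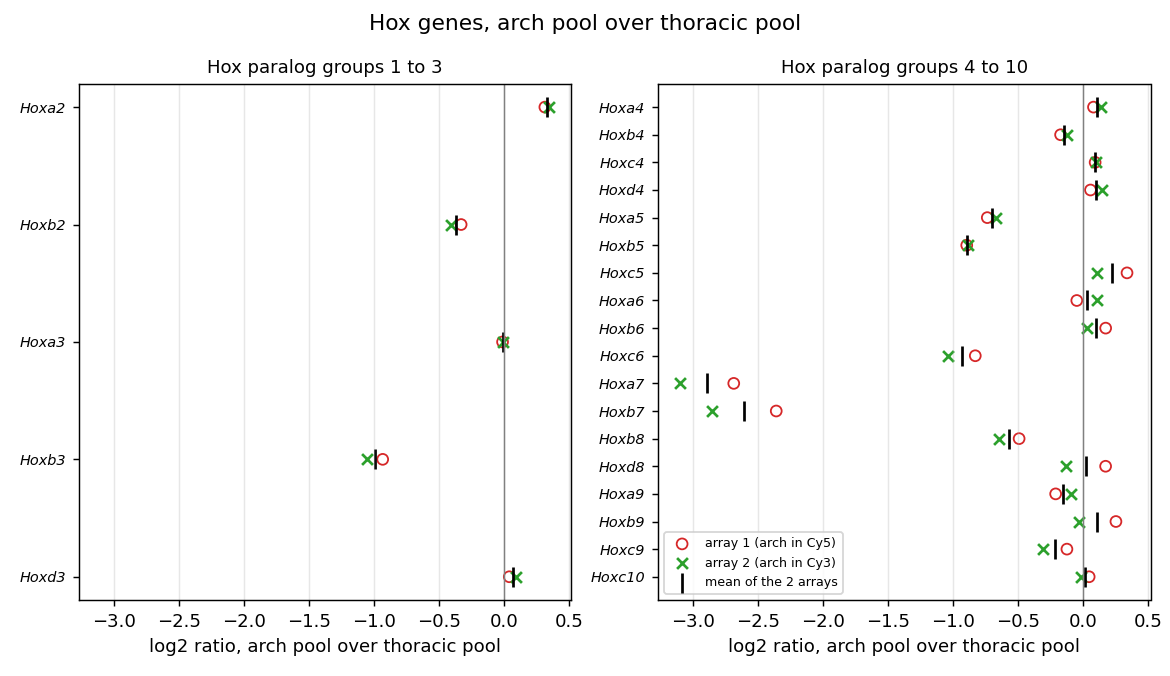
Log2 ratio of arch over thoracic pool (x axis) for measured Hox genes (y axis, in order of paralog group), with groups 1 to 3 on the left and 4 to 10 on the right, array 1 as open circles, array 2 as crosses and the mean as a bar. Hoxd4 and Hoxd8 were well above background in the arch pool only. Hoxa7 (−2.89) and Hoxb7 (−2.61) stand apart from the other members.

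Fat-cell transcripts were higher in the arch pool. Of 9 measured brown adipocyte markers 4 were higher by the rule, namely Cox7a1 (0.89 ± 0.05), Cidea (0.81 ± 0.03), Cox8b (0.78 ± 0.07) and Dio2 (0.76 ± 0.02). Of the 9 markers 7 were above 0, and the list's median was 0.41, at percentile 100. Of 10 adipocyte markers 3 were higher, Pck1 (0.78 ± 0.04), Plin1, which coats lipid droplets (0.68 ± 0.00), and the hormone Adipoq (0.66 ± 0.06), with a median of 0.41 at percentile 100. With median centring all of these but Cox7a1 lost their call and both medians were 0.24, still at percentile 100. Markers of mesothelium and epithelium, the lining of body cavities and other surfaces, had a median of 0.38 at percentile 100, and of 0.60 with an offset of 0. All 9 of their measured members were above 0, with Upk3b at 0.65 ± 0.12, Msln at 0.54 ± 0.05 and Krt19 at 0.43 ± 0.15, but none met the 1.5-fold rule on each array. With the scanner software's ratios Upk3b (0.96 ± 0.13) and Krt19 (0.88 ± 0.23) met it, and Msln (0.61 ± 0.06) did not. The lipid uptake, efflux and synthesis list had a median of 0.06 (percentile 99.1), which was 0.15 with an offset of 0, turned to −0.0048 with median centring and no longer stood apart on array 2 alone (0.04, percentile 91.3). Of its 17 measured genes 0 were called, with Apoe at 0.44 ± 0.06 and Scd1 at 0.42 ± 0.13.

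Of 15 measured cardiomyocyte markers, 3 were higher in the arch. These were Myl7, Tnnt2 and Sln, a regulator of the calcium pump (0.87 ± 0.04), while Nppa measured 0.28 ± 0.03. The list's median was 0.05 (percentile 99.3) and its mean 0.38. The median was 0.11 with an offset of 0, and on array 1 alone it no longer stood apart (percentile 95.1). Of 10 cartilage markers Cytl1 alone was called, Sox9 measured 0.31 ± 0.12 (0.06 at its lowest probe) and Comp 0.20 ± 0.11, and the median was 0.10 (percentile 99.9), 0.17 with an offset of 0 and 0.02 with median centring. Endothelial markers had a median of 0.06 (percentile 99.3), with 0 of 11 called and Vwf at 0.26 ± 0.02 (0.12 at another probe). That list no longer stood apart on array 1 alone (0.04, percentile 83.3), without the filter on dim probes (0.03, percentile 92.0) or with median centring (0.02, percentile 94.4). All 14 macrophage markers were below 0, with a median of −0.11 (percentile 0.02), −0.26 with median centring, and 0 called; Tyrobp measured −0.35 ± 0.03 and Lyz2 −0.29 ± 0.13.

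Genes of the smooth muscle contractile apparatus were close to equal in the pools. Their median was −0.09 (percentile 0.07) over 16 genes with 0 called, −0.25 with median centring, −0.14 on array 1 alone, and on array 2 alone −0.04, within the central 95% of random lists (percentile 12.9). Acta2 and Tagln measured 0.02 each, Myh11 −0.22 ± 0.03 and Pln 0.52 ± 0.02. With the scanner software's ratios Myh11 was −0.23 ± 0.03, but Pln was 1.71 ± 0.08. Genes of modulated or synthetic smooth muscle had a median of 0.13 (percentile 99.9). With median centring it was −0.03, still above the central 95% of random lists (percentile 99.7). Of 13 members S100a4 was higher (0.61 ± 0.02, not called with median centring or an offset of 0), and the matrix proteins Tnc (−0.90 ± 0.08) and Fn1 (−0.67 ± 0.05) were lower, each with another probe of opposite sign (0.09 and 0.10). Neither was called as the mean of its probes, and Tnc was 0.14 with the scanner software's ratios, where another probe was brightest. Neural crest and outflow tract regulators had a median of 0.12 (percentile 100), with 18 of 24 above 0 and 0 called. With median centring their median was 0.00, still high among random lists (percentile 99.65). Ednra, the endothelin receptor, measured 0.47 ± 0.08 with other probes near 0, Dlx5 0.44 ± 0.06 and Tbx18 −0.53 ± 0.06. The TGF-beta and BMP signalling list had a median of 0.04 (percentile 98.9), which was 0.08 with an offset of 0. Median centring turned it to −0.0079, which was still above the central 95% of random lists. The list no longer stood apart on array 1 alone (0.03, percentile 84.2). Its called member was Ltbp2 (0.78 ± 0.16, and −0.03 at another probe), of 22 measured, which was not called as the mean of its probes or with median centring.

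The list of immediate early and heat shock genes was lower in the arch pool, with a median of −0.30 (percentile 0) over 13 genes. Hspa1a was its only measured heat shock gene, so the median says little about heat shock genes. Btg2 (−0.80 ± 0.09, not called as the mean of its probes) and Nr4a1 (−0.66 ± 0.01) met the rule, and Fos (−0.62 ± 0.07) and Junb (−0.55 ± 0.07, and −1.12 at another probe) did not. With the scanner software's ratios Fos (−0.95 ± 0.11) met it and the brighter Junb probe (−0.56 ± 0.07) did not. Inflammatory and adhesion genes had a median of −0.15 (percentile 0), −0.26 with median centring, with 0 of 17 called, among them the chemokines Ccl2 (−0.61 ± 0.10) and Ccl8 (−0.47 ± 0.05). Both chemokines met the rule with the scanner software's ratios (−0.83 ± 0.10 and −0.69 ± 0.03). The complement and MHC class II list had a median of −0.07 (percentile 1.44) and a mean of 0.03, which differ in sign. Its member C3, the central complement protein, was higher in the arch at its brightest probe (0.72 ± 0.07) and 0.15 at another, and was not called as the mean of its probes or with median centring. That list did not stand apart on array 1 alone (−0.03, percentile 22.1), on array 2 alone (0.01, percentile 63.2) or with median centring (−0.18, percentile 15.8).

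Like Hox groups 1 to 3, the other 12 lists lay within the central 95% of their random lists. Medians were 0.00 for fibrillar and elastic matrix, where Fbln5 measured 0.65 ± 0.10 (0.08 at another probe) and Fmod −0.58 ± 0.05, 0.03 for vascular tone receptors and channels, with Rgs5 at −0.36 ± 0.07, and 0.02 for osteogenic and calcification regulators, with Alpl at 0.49 ± 0.02. They were −0.02 for proliferation, −0.01 for skeletal muscle, 0.04 for adventitial fibroblasts, −0.03 for lymphocytes, 0.05 for thymus and 0.04 for neurons and Schwann cells. Neurons and Schwann cells stood apart with an offset of 0 (0.09, percentile 98.1) and with the scanner software's ratios or the value table (0.12), and vascular tone genes as the mean over probes (0.04, percentile 98.8) or with a filter on both regions (0.05, percentile 99.0). Blood markers had a median of −0.01 and housekeeping genes 0.05. Sex-linked transcripts, a control for the make-up of the pools, lay between −0.07 (Xist) and 0.01 (Eif2s3y), with a median of 0.00.

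**Figure D3:**
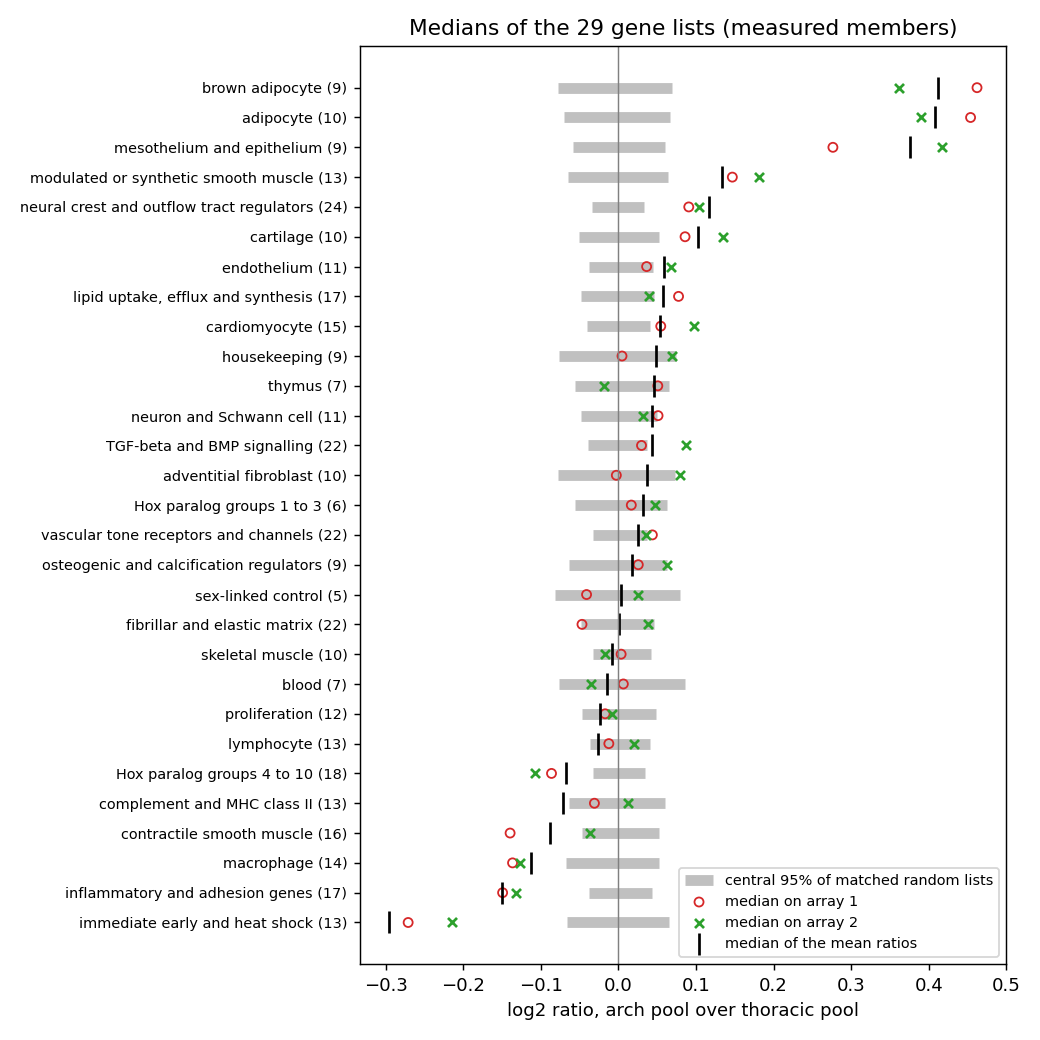
Median log2 ratio of arch over thoracic pool (x axis) for each of 29 gene lists (y axis, measured members in brackets), with array 1 as open circles, array 2 as crosses, the median of the mean ratios as a bar and the central 95% of matched random lists in grey. Brown adipocyte (0.41), adipocyte (0.41) and mesothelium and epithelium (0.38) lie highest and immediate early and heat shock (−0.30) lowest.

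Few genes were well above background in 1 region on both arrays and in the other region on neither, 14 in the arch and 16 in the thoracic aorta. For such genes the bound is the least difference, and the main offset shrinks it. The largest bounds were at least 1.17-fold for Rgs1 in the thoracic pool and at least 1.15-fold for Gdf2 in the arch pool. With an offset of 0 their log2 ratios were −1.01 and 1.09. The scanner software's ratios were −1.61 ± 0.25 for Rgs1 and 1.49 ± 0.13 for Gdf2. The dimmer region was not well above background, so these ratios are imprecise.

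The background offset shrank the ratios, more so for dimmer genes. With an offset of 0 the Hoxa7 ratio was −3.40, Hoxb7 −3.21, Myl7 3.10 and Stc2 2.05, and 116 genes were called higher and 103 lower. The scanner software's own ratios, which also differ in background and normalisation, gave 152 and 126. With median centring in place of loess 28 genes were called higher and 75 lower, so that 27.2% of calls were higher in the arch in place of 52.9%. The housekeeping median also moved down with median centring, from 0.05 to −0.10.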

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

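Against 55 genes higher and 49 lower in the arch and 0 following the dye, an offset of 0 gave 116, 103 and 2, the scanner software's ratios 152, 126 and 15, the deposited series values 152, 128 and 15, and median centring 28, 75 and 3. A 2-fold rule gave 9 higher and 15 lower, and a 1.3-fold rule 134, 112 and 3. Each array alone gave 72 to 81 higher and 62 to 67 lower. No gene called in one direction was called in the other under these alternatives. For the other folds and for each array alone the rule itself fixes this outcome. All 55 and 49 genes were among the calls of the value table, and 28 of the 55 and all 49 among those of median centring. Of 29 lists 16 stood apart from random lists, 12 to 17 under the alternatives, and 8 did so with the same sign under all 12: neural crest, inflammatory, immediate early, cartilage, macrophage, both fat lists and mesothelium, though neural crest was 0.00 and cartilage 0.02 with median centring. Hox groups 4 to 10 no longer stood apart with an offset of 0, the scanner ratios or no filter on dim probes (percentiles 3.82, 5.56 and 27.3) but did with the value table (0), where a different Hoxb8 probe was brightest, nor with one of the arrays alone did endothelium (83.3), contractile genes (12.9), TGF-beta and BMP signalling (84.2), lipid genes (91.3) or cardiomyocyte (95.1). Median centring turned modulated smooth muscle to −0.034, TGF-beta and BMP signalling to −0.0079 and lipid genes to −0.0048. All of these lists stayed above the central 95% of random lists under that setting. Complement and MHC class II ranged from −0.031 to 0.013 on single arrays. Tnc was 0.14 with the scanner ratios, where another of its probes was brightest. A single array cannot change the call or the sign of a called gene, since a call already needs 1.5-fold on each array. Of 43 called named genes, 29 kept their call under all 11 alternatives run for genes, which count both single arrays, and 42 their sign. Apart from Tnc and Hoxb8, the causes were not tested. Signal over background limits dim genes, whose ratios the offset shrinks.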

Other observations

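The lists in this part were chosen after seeing the data, and the tests of a dye bias, of the share of muscle cells and of heart muscle were chosen after the results they bear on. The list of other fat-enriched transcripts was added after the respiratory chain result was known, though none of its values had been looked at.

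Interferon-stimulated genes were slightly higher in the arch pool, with 17 of 19 measured members above 0, a median of 0.07 (percentile 99.96) and 0 called; Ifit1 measured 0.37 ± 0.05 and Bst2 0.35 ± 0.08. Wnt ligands and antagonists differed by member. Wif1, a secreted Wnt inhibitor, was higher in the arch (0.97 ± 0.10), Sfrp4 (−2.39 ± 0.04) and the ligand Wnt2 (−0.79 ± 0.04) were lower, and the median of 19 genes was 0.02 (percentile 85.1). Exocrine pancreas transcripts had a median of 0.03 (percentile 91.5) with 0 of 10 called.

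Liver-type transcripts were higher in the thoracic pool: 9 of 38 measured members of a list of abundant liver transcripts were above 0, the median was −0.16, and Mup1 (−1.83), Alb (−0.95) and Fabp1 (−0.63) were called lower in the arch. A gene-specific dye bias would turn the sign between the arrays and is argued against, since the list's median was −0.14 on array 1 (spread 0.05) and −0.16 on array 2. A trace of liver RNA in the thoracic pool is a candidate explanation: the 34 members not seen before had a median of −0.13 (percentile 0), beyond the bound of −0.10 fixed beforehand, though by less than the median's spread of 0.04. Cyp2e1 (0.43 ± 0.07) and Ahsg (0.36 ± 0.13) were above 0, which such a trace does not account for. Fga (0.01), Apob (0.00) and Trf (−0.03) were near 0, while 25 of the 34 were below 0. Fga and Apob were dim, with mean log2 intensities of 6.19 and 6.56 against a median of 7.01 over all genes, so their values weigh little. Ttr, also listed, was not well above background in either region. No step in the labels would remove such RNA, how many of these genes the aorta also expresses was not measured, and a regional difference in the aorta itself stays open and untested.

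Adipocyte transcripts were higher in the arch pool, with list medians of 0.41 and 0.41. A lower share of muscle cells, which would raise every other cell type alike, is argued against by the adventitial fibroblast, neuron and macrophage lists. Their medians were 0.04, 0.04 and −0.11, although mesothelium and epithelium stood at 0.38. The endothelium list, tested with them, was highest at 0.058. It cannot decide this, since the aortas were perfused with a detergent to remove the endothelium. More brown fat on the arch segment missed the bound fixed beforehand, a respiratory chain median over 0.10, which came out at 0.065 with a spread of 0.02 (44 of 52 genes above 0, percentile 99.99). After that result the bound was judged too strict, because these genes have a median intensity at percentile 97.3 of all genes, where a small share of fat is hidden, so brown fat is neither shown nor excluded. More fat tissue of any kind stays open too: the other fat-enriched list had a median of 0.11 (18 of 21 above 0), between its bounds of 0.10 and 0.20, and a difference between the regions themselves was not tested.

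In the arch pool 3 cardiomyocyte transcripts were higher, Myl7 (2.33), Tnnt2 (1.59) and Sln (0.87). Heart muscle attached to the arch segment would bring its other abundant transcripts too, but the 11 others measured had a median of 0.033 with a spread of 0.04, and all 14 a median of 0.08 with a spread of 0.10. Among matched random lists the 11 others stood at percentile 92.1, with 7 above 0. All 14, which include the 3 called transcripts, stood at percentile 99.9. With the main offset, the median of the 11 argues against heart muscle with its full set of transcripts as the whole source. Neither set was run with the alternatives, and the offset shrinks the ratios of dim genes. The cardiomyocyte list, which shares members with both, had a median of 0.05. It was 0.11 with an offset of 0 and 0.14 with the scanner software's ratios. Myh6 and Csrp3, the remaining members of the heart muscle list, were not well above background in either region. Nppa (0.28, and 0.01 at another probe) and Myl4 (0.24 and 0.32), atrial like Myl7 and Sln, were above 0 but not called, and atrial muscle was not tested on its own. By the labels the arch segment includes the root, and a difference between the regions themselves stays open and untested.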
